A study of Rattus norvegicus with 6 samples.

How the data were processed

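Poly(A) RNA of cultured neonatal rat ventricular cardiomyocytes was sequenced in 6 libraries, 3 from cells given vehicle and 3 from cells given perhexiline at 1 µM for 24 h, and each library was placed in its group by its label. Per the labels' protocols, RNA was extracted with TRIzol, kept where its integrity number was high, selected on oligo(dT) beads, fragmented and made into libraries with dUTP-marked second strands, which were read as pairs on an Illumina NovaSeq instrument.

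The values are FPKM per gene and library, as deposited by the authors, per the file headers, with 1 column per library and a gene length, biotype and coordinates for each of 34257 genes. Per the submitters' processing notes, HISAT2 2.0.5 and DESeq2 belonged to the processing, with no role stated. The genome build, the annotation and the counting program are not given in the sources used here, so whether counting used the strand is unknown, and reads shared by paralogs, pseudogenes, overlapping genes or antisense genes cannot be told apart. Of the genes, 11259 were at 0 in all libraries and 1374 had no name. A 0 can be a failed estimate, since a gene that most cells transcribe, Fth1, was among those at 0, and such genes are only said to be listed at 0.

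FPKM times gene length came out as whole multiples of 1 step per library, estimated from the 500 smallest positive values, for 100.0% of positive values within a tolerance of 0.01 (largest distance 0.0024). These multiples were taken as fragments. They gave the depth, from 13616252 to 16702523 fragments per library, and CPM values for the rule on named genes. The deposited scaling differed from median-of-ratios factors of these fragments by at most 0.94%, and from their totals by -3.4% to 2.9%. Replicates of a group were different libraries, with 0 identical values and a chi-square per degree of freedom of 4.7 to 8.14 between pairs.

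A count model had been planned on the assumption that the table held counts. It held FPKM, so the planned test for such values was used. Genes with an FPKM of at least 1 in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, robust fitting off, two-sided), with group as the only term, and called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds are ratios of mean FPKM. All adjusted p-values of single genes are from this limma fit and those of lists from camera in limma unless another tool is named.

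The 31 gene lists, the rule for named genes, the tests and most alternatives were set before the data were examined. The lists covered iron handling, ferroptosis, lipid synthesis and oxidation, stress responses, lysosome, mitochondria, glycolysis, sarcomere, hypertrophy, ion channels, inflammation, interferon, p53, heat shock, cell cycle, cell death, quality measures (immediate early and ribosomal protein genes) and 7 cell types other than cardiomyocytes. Of 965 symbols 915 were in the table, 13 of them mitochondrial names matched by alias after the table was seen. Lists with at least 5 tested members were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists), and again with a correlation estimated from the data. Members were counted over all genes and adjusted over the list alone. Lists could share genes, so their counts are not independent. Named genes were Trim28, Ireb2 and Tfrc, the 10 higher and 10 lower genes with the largest differences among called genes with a mean CPM of at least 5 and a real symbol, and up to 4 called members per list with the smallest adjusted p, or the 2 most abundant where none passed. Genes named outside this rule are said to be so. Shares of fragments were compared with exact permutation tests, two-sided, whose smallest p is 0.1 with 3 against 3 libraries.

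The procedure was tested on data simulated from these libraries, with 10 simulations of 200 changed genes among a median of 13463 tested. It called 40.4% of 1.5-fold changes, 65.8% of 2-fold and 88.3% of 4-fold changes, and 6.97% of its calls were false. These rates depend on the number of changed genes, which is unknown in the data. Genes of equal mean expression were also given the same spread, so the rates need not hold here. With no changed gene the procedure called at most 1 gene, and 0 of 304 list tests. The simulated genes varied independently of each other. The simulations therefore do not show how often camera falsely calls lists whose genes vary together, with estimated correlations of up to 0.596 here. The alternatives were other scalings, filters, pseudocounts and fold thresholds, limma-voom on the recovered fragments, the replicate number as a block, each library left out in turn, an estimated correlation and fry. Unnamed loci and genes with placeholder names were tested but not named, apart from 1 copy of Mff.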

Results

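Cultured ventricular heart muscle cells from newborn rats were exposed to perhexiline at 1 µM for 24 h or to vehicle, and their poly(A) RNA was sequenced. Perhexiline is an antianginal drug that inhibits carnitine palmitoyltransferase 1, the enzyme that admits long-chain fatty acids to mitochondria. There were 3 libraries per group. The table gave FPKM for 34257 genes, of which 11259 were at 0 in all 6 libraries. Fragments recovered from these values numbered 13616252 to 15241994 in the vehicle libraries and 14863929 to 16702523 in the perhexiline libraries, so 1 fragment on a gene of 1 kilobase was worth 0.0574 to 0.0727 FPKM. The labels do not say whether the replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

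The comparison asks how perhexiline changed the transcriptome of these cardiomyocytes. With perhexiline, 20 of 26 tested inflammation genes, 22 of 35 interferon-stimulated genes and 14 of 35 genes of the integrated stress response rose, and none of them fell. In the lists of sarcomere, calcium handling and oxidative phosphorylation genes, 12 of 33, 5 of 38 and 11 of 50 fell, and none rose. The largest rises included the neutrophil chemokine Cxcl1, from 10.3 ± 1.97 to 77.1 ± 39.6 FPKM (mean ± SD, n = 3 per group, as throughout), and the antiviral gene Rsad2, from 0.581 ± 0.0635 to 5.48 ± 1.57 FPKM. Most falls were smaller. Among named genes the sarcoplasmic reticulum gene Tecrl, from 17.3 ± 2.01 to 6.81 ± 0.919 FPKM, had the largest fall after Mff, whose reads are uncertain. Of 13460 genes tested with limma, 896 passed an adjusted p of 0.05, with 478 higher and 418 lower (53.3% higher). The perhexiline and vehicle libraries did not overlap for any of the 896, which the selection of these genes by the test favours. Of all tested genes, 4289 (31.9%) did not overlap, against 10% expected by chance. Of the 896 called genes, 44 higher and 14 lower ones reached a log2 difference of 1, and their median absolute difference was 0.42. The count fell to 117 without vehicle replicate 1, 142 without vehicle replicate 2, 125 without perhexiline replicate 2 and 87 without perhexiline replicate 3. The share of higher genes was 42.0% under upper-quartile scaling and 70.7% under total-fragment scaling, while the median log2 difference of all genes stayed between -0.02 and 0.06. The count was 162 without the filter on low values and 1562 with limma-voom on the recovered fragments. Of 30 gene lists fixed before the data were examined and tested, camera called 11 higher and 9 lower with a preset correlation between genes, and 0 with an estimated correlation.

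**Figure D1:**
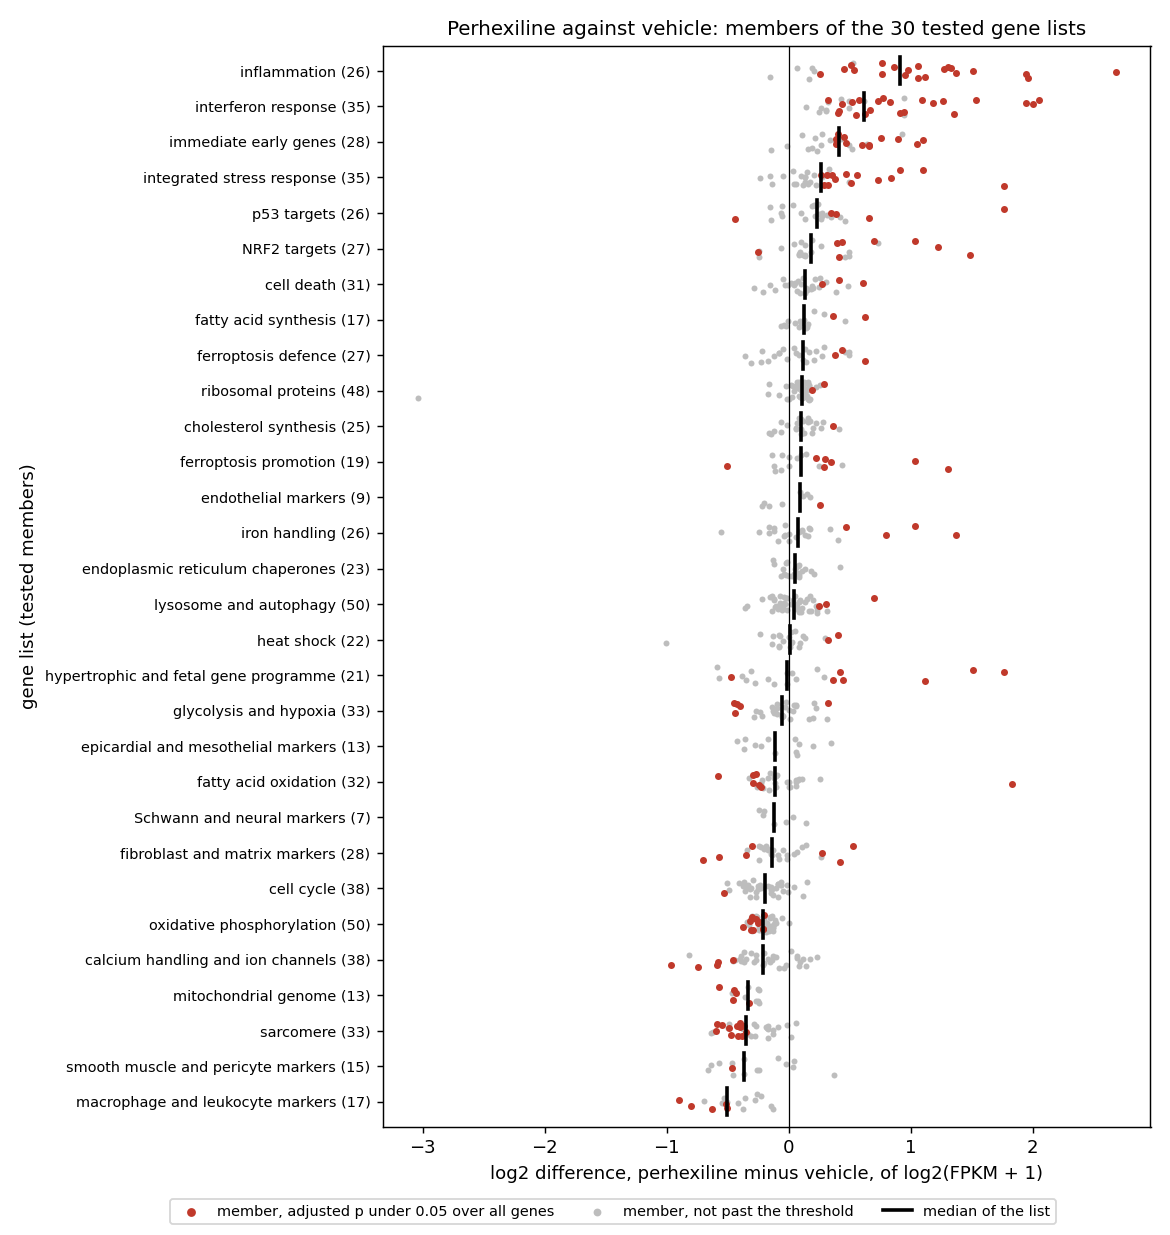
Log2 differences (perhexiline minus vehicle, of log2(FPKM + 1), horizontal axis) of the tested members of 30 gene lists (vertical axis, number of tested members in parentheses). Points are genes, in colour where the adjusted p over all genes was under 0.05, and black bars are list medians, from 0.91 for inflammation down to -0.51 for macrophage and leukocyte markers.

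Most tested genes of inflammation and of the interferon response rose. Of 26 tested targets of the inflammatory transcription factor NF-kB, 20 rose and none fell, with a median log2 difference of 0.91. Cxcl10, a T cell chemokine, went from 7.09 ± 1.92 to 30.1 ± 6.62 FPKM, the iron-binding lipocalin Lcn2 from 119 ± 17.7 to 309.9 ± 52.0, and the adhesion molecule Icam1 from 30.8 ± 2.19 to 53.2 ± 4.97. The cytokine Il6 went from 0.502 ± 0.274 to 3.28 ± 0.856 FPKM, and Nfkb2, a subunit of NF-kB itself, rose 1.45-fold. Of 35 tested interferon-stimulated genes, 22 rose and none fell, with a median of 0.61 and all 35 differences above 0. The antiviral genes Ifit3 and Oasl went from 1.04 ± 0.266 to 7.61 ± 2.16 and from 1.15 ± 0.252 to 5.28 ± 1.14 FPKM, and the guanylate-binding protein gene Gbp2 from 5.98 ± 0.313 to 9.77 ± 0.115. Adjusted over the list alone, 21 inflammation genes and 30 interferon genes were higher and none was lower. Both lists passed camera (adjusted p = 1.93e-16 for inflammation and 1.61e-20 for interferon; adjusted p = 0.223 for each with an estimated correlation). Lcn2, Icam1, Nfkb2, Il6, Cxcl10, Ifit3, Rsad2, Oasl and Gbp2 stayed under an adjusted p of 0.05 in all 6 fits without 1 library, with 0.0499 for Il6 as the highest value. Cxcl1 reached 0.0508 without perhexiline replicate 3. The inflammation count was 13, 11, 11 and 7, and the interferon count 11, 9, 10 and 7, without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 and perhexiline replicate 3, in that order. With no filter on low values, 11 inflammation and 8 interferon genes rose. Markers of macrophages and other leukocytes moved the opposite way in the same libraries, with a mean log2 difference of -0.46 ± 0.14 (SE over libraries).

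Several genes of stress response lists rose. Among 35 tested targets of the integrated stress response, the programme of the transcription factors ATF4 and CHOP, 14 rose and none fell, and 20 were higher when adjusted over the list alone. Gdf15, a secreted stress cytokine, went from 32.3 ± 4.32 to 115 ± 32.8 FPKM. Ddit4, an inhibitor of mTORC1 signalling, went from 10.8 ± 0.721 to 21.2 ± 1.36, and the transcription factor Cebpb from 60.8 ± 3.58 to 109.7 ± 14.8. Among 27 targets of the antioxidant regulator NRF2, 7 rose and 1 fell, against 11 and 2 adjusted over the list alone. The metal-binding metallothioneins led them, with Mt2A at 189 ± 10.9 against 445 ± 38.7 FPKM and Mt1 at 16.5 ± 0.431 against 48.7 ± 8.99. Metallothionein genes are close paralogs, so the split of reads between them is uncertain. The mitochondrial superoxide dismutase Sod2 rose 1.32-fold. The other rises in this list were those of Ugdh, Sqstm1, Gclc and Hmox1. Nqo1, Gclm, Txnrd1 and Slc7a11, also in the list and named after the results were seen, were not among the genes that passed. Immediate early genes, which also respond to handling, had 12 rises and no fall among 28 (17 higher adjusted over the list alone), among them Myc, from 9.47 ± 0.972 to 20.7 ± 2.25 FPKM, and Atf3, from 5.37 ± 1.08 to 12.7 ± 1.73. Camera called all 3 lists higher, with adjusted p = 9.81e-10 for the integrated stress response (adjusted p = 0.223 with an estimated correlation), 1.28e-05 for NRF2 targets (0.327) and 8.45e-11 for immediate early genes (0.327). Without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 and perhexiline replicate 3, the rises numbered 5, 5, 3 and 3 in the integrated stress response, 3, 4, 4 and 4 among NRF2 targets and 3, 2, 2 and 1 among immediate early genes, in that order. NRF2 targets with a rise numbered 13 without vehicle replicate 3. With no filter on low values the rises numbered 6, 4 and 3 in the 3 lists. Gdf15, Ddit4, Cebpb, Mt2A, Mt1, Sod2 and Myc passed in all 6 of those fits, with adjusted p of up to 0.0498 for Gdf15, and Atf3 lost its call without perhexiline replicate 2 or perhexiline replicate 3 (highest adjusted p = 0.0584). None of the 23 tested endoplasmic reticulum chaperones passed (camera adjusted p = 0.238), over all genes or adjusted over the list alone, and the chaperone Hspa5 stood at 257 ± 23.2 and 271 ± 12.4 FPKM. Camera called this list higher without vehicle replicate 1 (adjusted p = 0.0414) or perhexiline replicate 3 (0.026).

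Some targets of p53 and a few cell death genes rose. Of 26 tested p53 targets, 4 rose and 1 fell (10 and 1 adjusted over the list alone; list median 0.23). The rises were those of Gdf15 (3.56-fold), Sat1 (1.28-fold), the antiproliferative gene Btg2 (1.62-fold, named after its values were seen) and the growth arrest gene Gadd45a, from 95.5 ± 2.84 to 126 ± 11.6 FPKM, and the fall was that of the adhesion gene Perp, from 37.7 ± 2.99 to 27.5 ± 1.56. Gdf15 also belongs to the integrated stress response and hypertrophic lists, Sat1 to the ferroptosis-promoting genes and Btg2 to the immediate early genes. Of 31 cell death genes, 3 rose and none fell (7 and 1 adjusted over the list alone), against 5 rises under total-fragment scaling, 6 rises and 1 fall with limma-voom and 0 with no filter on low values. The rises were those of Casp4, an inflammatory caspase, which went from 3.08 ± 0.113 to 5.25 ± 0.618 FPKM, the tumour necrosis factor receptor gene Tnfrsf1a, which rose 1.21-fold, and Mlkl, the executor of necroptosis, which rose 1.37-fold. Camera called both lists higher (adjusted p = 3e-04 and 0.00294; adjusted p = 0.327 for each with an estimated correlation). Gadd45a, Perp, Casp4, Tnfrsf1a and Mlkl each lost the call without vehicle replicate 1, vehicle replicate 2 or perhexiline replicate 3, with adjusted p up to 0.0872, and no cell death gene passed in those fits. The p53 targets with a rise numbered 9 with limma-voom, 8 with a mean FPKM of at least 5, 2 with no filter and 1 without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 or perhexiline replicate 3.

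The series is framed around ferroptosis, an iron-dependent form of cell death, and the genes Trim28, Ireb2 and Tfrc, and none of the 3 passed the test at the RNA level. Trim28 encodes a transcriptional corepressor and ubiquitin ligase (chromosome 1, 65544373 to 65551043). It stood at 123 ± 4.25 FPKM with vehicle and 133 ± 1.69 with perhexiline, a log2 difference of 0.12 ± 0.045 (SE; limma adjusted p = 0.146, unadjusted p = 0.0297). Ireb2 encodes the iron sensor IRP2 (chromosome 8, 59420123 to 59501118) and stood at 31.9 ± 0.914 and 30.05 ± 0.181 FPKM (adjusted p = 0.299). Tfrc encodes the transferrin receptor TFR1, which imports iron (chromosome 11, 71397383 to 71419223), and stood at 85.1 ± 6.32 and 78.0 ± 3.23 FPKM (adjusted p = 0.282). The coordinates are those of the deposited table, whose genome build is not given in the sources used here, and protein was not measured in these libraries.

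Iron and ferroptosis genes changed in part. Several of them belong to other lists as well: Lcn2 and Ptgs2 to inflammation, Hmox1 to NRF2 targets and Sat1 to p53 targets. Among 26 tested iron handling genes, 4 rose and none fell (6 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.133). Besides Lcn2 the rises were those of the haem-degrading enzyme Hmox1, from 200.2 ± 68.6 to 399.6 ± 59.4 FPKM, the metal importer Slc39a14, which rose 1.40-fold, and the iron hormone Hamp, from 70.4 ± 8.93 to 124 ± 27.6. Hamp passed in none of the 6 fits without 1 library (adjusted p up to 0.098). Hmox1 passed in 2 of these fits and Slc39a14 in 3, with limma adjusted p of up to 0.13 and 0.0617. Ferroptosis-promoting genes had 6 rises and 1 fall among 19 (7 and 2 adjusted over the list alone), with the prostaglandin synthase Ptgs2 going from 1.96 ± 0.442 to 6.45 ± 1.97 FPKM and the polyamine acetyltransferase Sat1 from 55.4 ± 1.52 to 70.8 ± 3.55. Camera called this list higher at adjusted p = 0.0455 (adjusted p = 0.327 with an estimated correlation), and the call was lost without vehicle replicate 2 (0.0928), vehicle replicate 3 (0.0511) or perhexiline replicate 2 (0.0695), with no filter on low values (0.0542) and with a mean FPKM of at least 5 (0.125). Acsl4, which channels polyunsaturated fatty acids into membranes, stood at 15.99 ± 1.05 and 19.3 ± 2.65 FPKM and did not pass (adjusted p = 0.165). Ferroptosis defence genes had 3 rises and no fall among 27 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0576). Camera called the defence list higher without vehicle replicate 1 (0.0414), vehicle replicate 3 (0.026) or perhexiline replicate 2 (0.0493), under upper-quartile scaling (0.0459) and with limma-voom (0.0317). The rises were those of Slc3a2, the heavy chain of the cystine importer, which rose 1.30-fold, Gclc, a subunit of the first enzyme of glutathione synthesis, which rose 1.36-fold, and the fatty acid desaturase Scd, which rose 1.58-fold. The peroxidase gene Gpx4 and the ferritin gene Fth1, transcribed in most cells, could not be read, since Fth1 was listed at 0 in all 6 libraries and Gpx4 at 0.0651 to 0.495 FPKM. Acsl4, Gpx4 and Fth1 were chosen after their values were seen. Without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 and perhexiline replicate 3, the rises numbered 1, 1, 2 and 1 among iron handling genes, 1, 0, 1 and 0 among ferroptosis-promoting genes and 1, 0, 0 and 0 among defence genes, in that order. Without vehicle replicate 3, ferroptosis-promoting and defence genes had 3 and 6 rises, and defence genes had 5 without perhexiline replicate 1. Defence genes had 5 rises under total-fragment scaling, 7 rises and 1 fall with limma-voom and 0 with no filter on low values. With no filter, 2 iron handling genes and 1 ferroptosis-promoting gene rose.

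**Figure D2:**
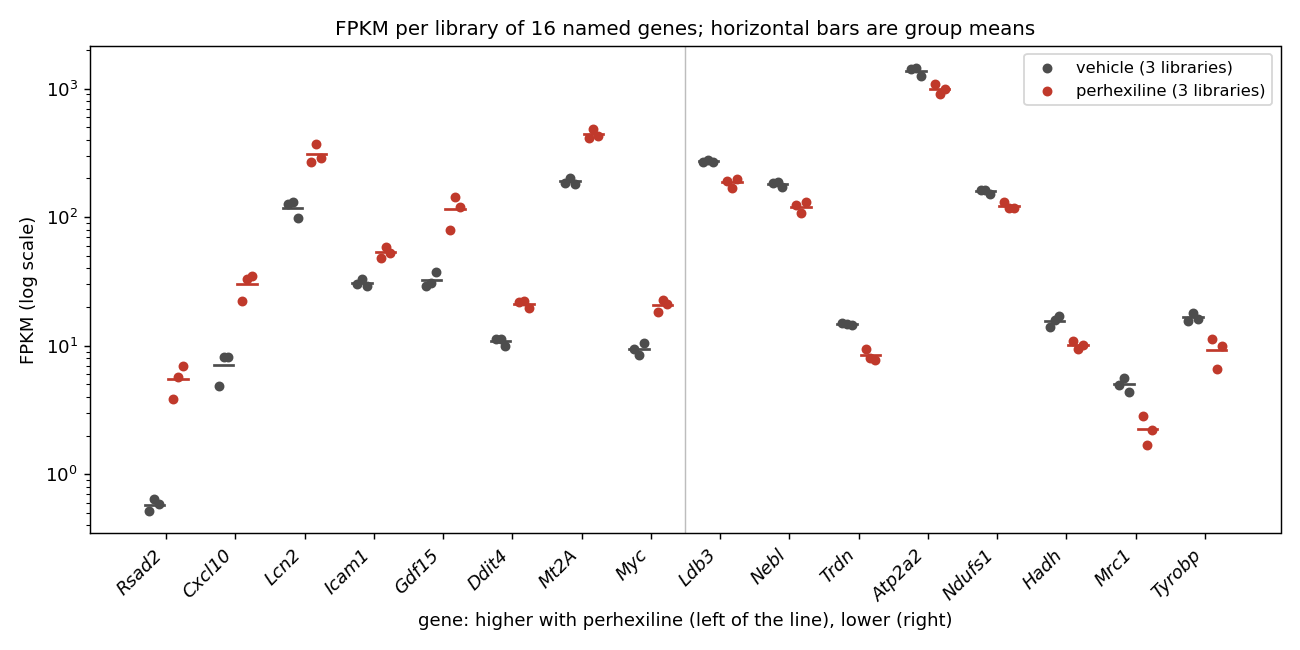
FPKM of 16 named genes in each of the 6 libraries (vertical log axis), with vehicle in grey, perhexiline in red and horizontal bars at the group means. All 16 genes had passed the test, a selection that favours separate groups. In each, the 3 perhexiline libraries lie on one side of the 3 vehicle libraries, as for Ldb3 at 271 ± 4.76 against 186 ± 16.4 FPKM.

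Part of the genes of the contractile apparatus fell. Of 33 tested sarcomere genes, 12 fell and none rose, 22 were lower when adjusted over the list alone, and the median log2 difference was -0.35. The Z-disc genes Ldb3 and Nebl went from 271 ± 4.76 to 186 ± 16.4 and from 181 ± 7.24 to 120.5 ± 11.7 FPKM, and Nexn, which binds actin filaments, from 272 ± 15.6 to 195 ± 9.34. Fhl2, a LIM-domain protein of the sarcomere, went from 323 ± 3.73 to 248 ± 6.47 FPKM. Of 38 tested calcium handling and ion channel genes, 5 fell and none rose, with 16 lower adjusted over the list alone. Trdn, which anchors the calcium store protein to the release channel, went from 14.7 ± 0.234 to 8.41 ± 0.939 FPKM, and that store protein's gene Casq2 from 384 ± 42.1 to 257 ± 28.5. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, went from 11.9 ± 1.45 to 5.64 ± 1.14, and the calcium pump gene Atp2a2 had 0.73 times its vehicle mean. The natriuretic peptide gene Nppa, a hypertrophy marker, stood at 2883 ± 700.1 and 3338 ± 467 FPKM (adjusted p = 0.469) and was chosen after its values were seen. Genes of the hypertrophic and fetal programme had 6 rises and 1 fall among 21 (6 and 6 adjusted over the list alone; camera adjusted p = 0.871), with a mean of 0.14 and a median of -0.01 that was 0.04 under total-fragment scaling. The rises included Gdf15, Il6 and the protease inhibitor Timp1, and the fall was that of the transcription factor Mef2c, from 19.9 ± 0.611 to 14.1 ± 0.889 FPKM. Camera called the sarcomere list (adjusted p = 9.37e-13) and the calcium list (1.22e-06) lower, with adjusted p = 0.327 for each with an estimated correlation. Without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 and perhexiline replicate 3, the falls numbered 3, 4, 5 and 3 among sarcomere genes and 1, 1, 2 and 2 among calcium genes, in that order, and without vehicle replicate 3 there were 8 calcium genes. In the hypertrophic list the rises numbered 3, 2, 2 and 3 in the same order, and the falls 4 without vehicle replicate 3 or perhexiline replicate 1. Ldb3, Fhl2 and Trdn passed in all 6 of those fits, with adjusted p of at most 0.0473, while Hrc, Casq2 and Atp2a2 lost their calls in 3 or more fits, with adjusted p of up to 0.101. Nebl reached 0.0503 without vehicle replicate 1, and Nexn 0.0543 without perhexiline replicate 3. With no filter on low values 4 sarcomere and 1 calcium genes fell, and with limma-voom 19 and 13 fell, while upper-quartile scaling and a mean FPKM of at least 5 each gave 8 calcium genes. With limma-voom the hypertrophic list had 6 rises and 6 falls, with a mean FPKM of at least 5 it had 5 of each, and with no filter 3 rises and 1 fall. In the same libraries the median log2 differences of macrophage, smooth muscle and fibroblast markers were -0.51, -0.36 and -0.13, with 17 of 17, 12 of 15 and 20 of 28 differences below 0. The smooth muscle list, as defined, shares Des and Myl9 with the sarcomere list and Abcc9 with the calcium list.

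Some markers of other cell types fell, and a few rose. Of 17 tested macrophage and leukocyte markers 5 fell and none rose (10 and 0 adjusted over the list alone; camera adjusted p = 1.59e-07, and adjusted p = 0.327 with an estimated correlation). The mannose receptor Mrc1 went from 5.01 ± 0.638 to 2.24 ± 0.568 FPKM and the myeloid adaptor Tyrobp from 16.6 ± 1.24 to 9.28 ± 2.39. Smooth muscle and pericyte markers had 1 fall among 15 (6 lower adjusted over the list alone), the actin-binding gene Synpo2 from 83.1 ± 5.33 to 60.02 ± 5.95 FPKM (list median -0.36, camera adjusted p = 0.00092; adjusted p = 0.327 with an estimated correlation). As defined, the smooth muscle list shares Des and Myl9 with the sarcomere list and Abcc9 with the calcium list. It is therefore not a measure of other cell types alone. Fibroblast and matrix markers went both ways, with 3 rises and 4 falls among 28 (4 and 8 adjusted over the list alone). The proteoglycan Dcn went from 93.1 ± 8.90 to 134 ± 3.75 FPKM and the collagen Col3a1 from 195 ± 4.93 to 153 ± 11.1 (list median -0.13, camera adjusted p = 0.0327; adjusted p = 0.327 with an estimated correlation). The fibroblast call was lost without vehicle replicate 2 (0.0653), vehicle replicate 3 (0.0562) or perhexiline replicate 2 (0.0609), and with a mean FPKM of at least 5 (0.101). Camera called neither endothelial markers (1 rise among 9, and 1 adjusted over the list alone), nor epicardial markers (0 among 13, and 1 higher and 2 lower adjusted over the list alone), nor Schwann cell and neural markers (0 among 7 either way), with adjusted p = 0.548, 0.256 and 0.277. It called the epicardial list lower without perhexiline replicate 1 (0.0225). Of erythroid markers only 4 could be tested, too few for camera, with 1 rise over all genes, 2 adjusted over the list alone and a median of 0.48. The endothelial rise was lost in all fits without 1 library except that without vehicle replicate 3, and the erythroid rise in all except that without vehicle replicate 2. Macrophage markers with a fall numbered 0, 0, 3, 1 and 0 without vehicle replicate 1, vehicle replicate 2, vehicle replicate 3, perhexiline replicate 2 and perhexiline replicate 3, in that order. Smooth muscle markers with a fall numbered 5 without vehicle replicate 3 or perhexiline replicate 1, and 0 in the other 4 fits. With limma-voom 8 macrophage and 6 smooth muscle markers fell, with a mean FPKM of at least 5 both had 3 falls, and with no filter on low values 1 and 0 fell. Fibroblast markers had 1 rise and 0 falls with no filter. Fibroblast markers had no more than 1 rise and 1 fall without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 or perhexiline replicate 3.

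Part of the respiratory chain transcripts fell. Of 50 tested nuclear genes of oxidative phosphorylation, 11 fell and none rose over all genes, 36 were lower adjusted over the list alone, and 49 of the 50 differences were below 0. Ndufs1 of complex I went from 159 ± 5.53 to 122 ± 8.12 FPKM, Sdha of complex II from 369 ± 14.2 to 299 ± 9.24 and Uqcrc2 of complex III from 229 ± 7.21 to 185 ± 9.52. All 13 mRNAs of the mitochondrial genome were lower, 5 of them past the test over all genes and 13 adjusted over the list alone. The falls numbered 6 in oxidative phosphorylation and 3 in the mitochondrial genome under total-fragment scaling, 20 and 10 with limma-voom, 17 and 8 with a mean FPKM of at least 5, and 1 and 0 with no filter on low values. COX2 went from 7427 ± 608 to 5004 ± 447 FPKM and ATP6 from 10954 ± 859.5 to 7960.4 ± 525. These mRNAs made up 7.29% ± 0.479 of fragments with vehicle and 5.90% ± 0.478 with perhexiline (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow). Both mitochondrial rRNAs moved the opposite way, the small one (mitochondrial chromosome, 68 to 1025) from 455 ± 33.9 to 692 ± 72.3 FPKM (adjusted p = 0.0185) and the large one (1094 to 2664) from 646 ± 59.97 to 964 ± 143 (adjusted p = 0.0355). Poly(A) selection removes most rRNA, so these values also depend on the selection, and overlapping mitochondrial genes such as ATP8 and ATP6 may share reads.

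**Figure D3:**
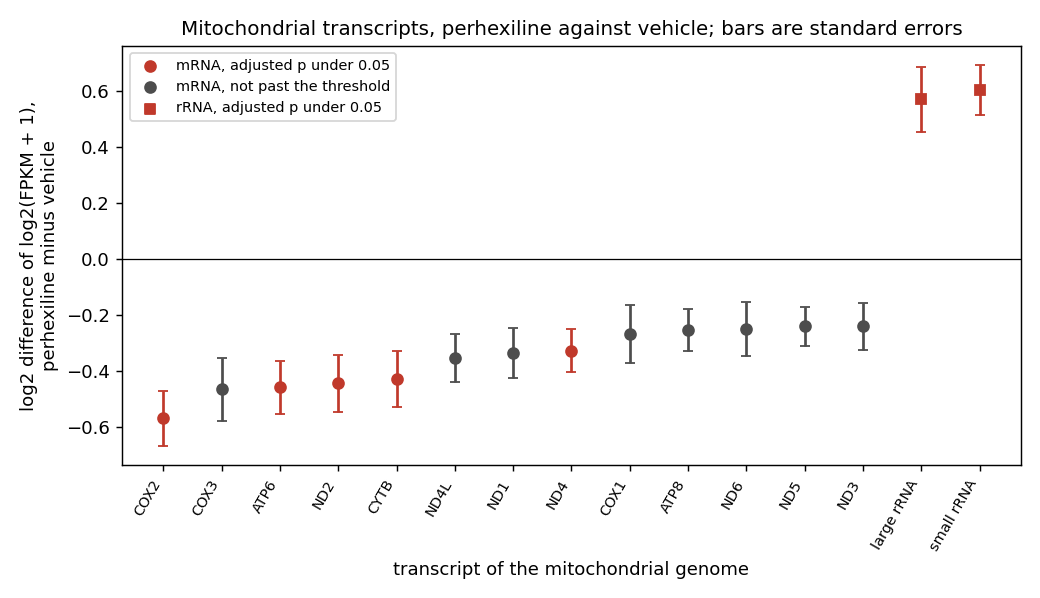
Log2 difference of log2(FPKM + 1), perhexiline minus vehicle (vertical axis), for the 13 mRNAs (circles) and 2 rRNAs (squares) of the mitochondrial genome, in red where the adjusted p was under 0.05, with standard errors as bars. The mRNAs lie between -0.57 and -0.24 and the rRNAs at 0.57 and 0.60.

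Among 32 tested genes of fatty acid oxidation, the pathway downstream of the drug's target, 1 rose and 6 fell (1 and 12 adjusted over the list alone), and 11 differences were above 0. Under total-fragment scaling 3 fell, and with no filter on low values 0 fell. The rise was that of Angptl4, a lipoprotein lipase inhibitor induced by fatty acids, from 3.90 ± 0.925 to 16.3 ± 2.38 FPKM, with an adjusted p of at most 0.0318 in all 6 fits without 1 library. The falls included the beta-oxidation enzymes Hadh, from 15.6 ± 1.56 to 10.1 ± 0.751 FPKM, and Acadm, from 87.1 ± 2.06 to 70.9 ± 3.23. The carnitine palmitoyltransferase genes Cpt1a and Cpt1b stood at 49.6 ± 5.02 and 53.4 ± 2.85 FPKM and at 71.0 ± 9.13 and 73.7 ± 3.46, and did not pass (adjusted p = 0.419 and 0.715); both were chosen after their values were seen. Camera called oxidative phosphorylation (adjusted p = 2.38e-16), the mitochondrial genome (1.97e-08) and fatty acid oxidation (0.00081) lower, with adjusted p = 0.327, 0.327 and 0.346 with an estimated correlation. Without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 and perhexiline replicate 3, the falls in oxidative phosphorylation numbered 0, 1, 0 and 0, those in the mitochondrial genome 0 each time and those in fatty acid oxidation 1, 0, 0 and 0, in that order. Without vehicle replicate 3 they numbered 9, 1 and 3, and without perhexiline replicate 1 they numbered 18, 7 and 5. Glycolysis and hypoxia genes had 1 rise and 4 falls among 33 (2 and 4 adjusted over the list alone; camera adjusted p = 0.0618), with the muscle phosphofructokinase gene Pfkm at 79.8 ± 7.15 against 59.1 ± 4.93 FPKM and a median of -0.05 that was 0.00 under total-fragment scaling. Camera called this list lower without vehicle replicate 3 (0.0175) or perhexiline replicate 2 (0.0325), under upper-quartile scaling (0.0375) and with a mean FPKM of at least 5 (0.0437), while no member passed with no filter on low values or without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 or perhexiline replicate 3.

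Few genes of lipid synthesis, proliferation and the remaining groups passed the test. Camera called fatty acid synthesis (2 rises among 17, and 2 adjusted over the list alone) and cholesterol synthesis (1 rise among 25, and 5 adjusted over the list alone) higher, with adjusted p = 0.00421 and 0.00479, and adjusted p = 0.327 and 0.346 with an estimated correlation. The passing genes were Scd, the fatty acid synthase Fasn, from 49.6 ± 0.677 to 64.3 ± 6.75 FPKM, and the sterol isomerase Ebp, from 11.8 ± 0.526 to 15.5 ± 1.00. Cell cycle genes had 1 fall among 38, the mitotic cyclin Ccnb1 from 5.61 ± 0.622 to 3.59 ± 0.599 FPKM, and 0 adjusted over the list alone. The Ccnb1 call was lost under total-fragment scaling (adjusted p = 0.0534), while 4 genes fell without perhexiline replicate 1, 2 under upper-quartile scaling and 7 with limma-voom. In this list 35 differences were below 0 (median -0.20, camera adjusted p = 3.9e-06; adjusted p = 0.223 with an estimated correlation). Ribosomal protein genes had 2 rises among 48, Rpl13a and Rpl28, and 0 adjusted over the list alone (median 0.11, mean 0.03, camera adjusted p = 1.15e-05; adjusted p = 0.327 with an estimated correlation), with 8 rises under total-fragment scaling. Neither gene passed under upper-quartile scaling or in any fit without 1 library. Lysosome and autophagy genes had 3 rises among 50 (3 and 1 lower adjusted over the list alone, and 5 rises under total-fragment scaling; camera adjusted p = 0.301), led by the autophagy receptor Sqstm1, from 225 ± 36.9 to 366 ± 45.1 FPKM. Heat shock genes had 2 rises among 22 (2 adjusted over the list alone), with a median of 0.01 that was -0.02 under upper-quartile scaling, a mean of -0.01 and a camera adjusted p of 0.699. With limma-voom, 4 fatty acid synthesis and 3 cholesterol genes rose. Without vehicle replicate 1, vehicle replicate 2, perhexiline replicate 2 or perhexiline replicate 3, fatty acid synthesis had at most 1 rise, and the cholesterol, cell cycle, ribosomal, lysosome and heat shock lists had no passing member. With no filter on low values none of these lists had one.

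Mff, a receptor for the fission machinery of mitochondria (chromosome 9, 90880614 to 90908852), had the largest fall among the named genes, but its reads are uncertain. It went from 28.2 ± 15.5 to 2.27 ± 2.37 FPKM (limma adjusted p = 0.0207), and lost the call without vehicle replicate 1, vehicle replicate 2 or perhexiline replicate 2 (highest adjusted p = 0.0730). A second locus on the same chromosome (88493593 to 88517827), described in the table as similar to Mff, held 867 fragments in perhexiline replicate 1, where Mff held 22, and at most 28 in the other 5 libraries. Of the 94 named genes that passed, 23 passed in all 6 fits without 1 library, and 32, 34, 80, 89, 35 and 27 passed without vehicle replicates 1, 2 and 3 and perhexiline replicates 1, 2 and 3.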

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

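Total-fragment scaling, with and without the mitochondrial genome, was chosen after seeing the data, and all other alternatives before. The planned count models were not run because the table holds FPKM, and median-of-ratios factors of the recovered fragments were run in place of that scaling. Genes called numbered 896 (478 higher, 418 lower). They numbered 162 (99 and 63) with no filter on low values, where 22998 genes were tested, 1562 (757 and 805) with limma-voom on recovered fragments, of which 851 were shared, and 58 (44 and 14) with a log2 difference of at least 1. Total-fragment scaling called 815 higher and 337 lower. Leaving out 1 library gave 87 (without perhexiline replicate 3) to 841 (without vehicle replicate 3) called genes, with 56 to 416 higher and 30 to 449 lower; fewer libraries were compared, and beyond that the cause was not tested. Camera called 20 lists, 18 to 22 under the other alternatives and 0 with an estimated correlation. Fry, which compares no list with other genes, called 20, of which 17 were shared: fatty acid oxidation (0.132), smooth muscle (0.101) and cholesterol synthesis (0.0804) were lost, and iron handling (0.0299), ferroptosis defence (0.0234) and Schwann markers (0.0462) gained. No list call reversed. The depth limits genes near 1 FPKM, and in simulations with 200 changed genes 40.4% of 1.5-fold changes were called, a rate that need not hold here.

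With the replicate number as a block, 173 genes were called (101 higher, 72 lower), 162 of them shared, and of the lists only ferroptosis promotion lost its call (adjusted p = 0.0528). The same-numbered libraries' deviations correlated at -0.0228, -0.101 and -0.0387, and no library correlated best with its own number. No pairing by number was seen. With 3 libraries per group this cannot exclude a shared culture, animal or batch.

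The 10 splits of the 6 libraries are too few for a share under 0.05. For genes called, the real split gave 896 and the highest of the others 1, so 1 of the 10 splits gave as many. For lists called, the real split gave 20 and the highest of the others 18, so again 1 of 10. All other splits mixed vehicle and perhexiline libraries. A real group difference would then widen the spread within each mixed group, which favours few gene calls. Part of that difference would also remain between the mixed groups, so these counts are not what no effect would give.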

Other observations

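The tests on leukocytes, scaling, cell shares and the Mff copy, and those of transcription factor families, were chosen only after the results were seen. Among genes outside the lists and the naming rule, chosen after their values were seen, the stress-induced adaptor Sfn went from 1.02 ± 0.226 to 7.74 ± 1.68 FPKM (limma adjusted p = 0.00494). Gfpt2 and Uap1, enzymes of the hexosamine pathway, went from 18.9 ± 2.55 to 47.9 ± 5.86 (0.00665) and from 18.6 ± 1.44 to 32.6 ± 4.63 FPKM (0.016). The bradykinin receptors Bdkrb1 and Bdkrb2 went from 0.533 ± 0.253 to 2.10 ± 0.430 (0.0233) and from 2.95 ± 0.430 to 6.66 ± 0.929 FPKM (0.0125). Lower genes included Tnni3k, a cardiac kinase that binds troponin I, from 23.7 ± 1.97 to 13.2 ± 2.63 FPKM (0.0217), and Pde3a, a cyclic nucleotide phosphodiesterase, from 30.8 ± 3.22 to 18.7 ± 3.89 (0.0373). Of 13 transcription factor families in the table with at least 10 tested members, camera called TF_bZIP, with 8 rises and no fall among 36 and a median log2 difference of 0.19 (adjusted p = 6.11e-06; adjusted p = 0.312 with an estimated correlation). This family may share genes with the stress response and immediate early lists, and the overlap was not counted.

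Of the inflammation and interferon genes, 20 of 26 and 22 of 35 rose. A larger number of leukocytes in the perhexiline cultures would raise leukocyte markers, but their mean log2 difference was -0.459 (SE 0.141). The deposited scaling as the whole cause is argued against by the inflammation list's median, which stayed at 0.891 or above under the other scalings. A response of the cultured cells to perhexiline is a candidate explanation and remains a hypothesis, with the source cell type open.

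Of the sarcomere genes, 12 of 33 fell. A lower share of cardiomyocytes as the only change would raise markers of every other cell type alike. The mean log2 differences were -0.0899 (SE 0.0233) for fibroblast and -0.459 (SE 0.141) for macrophage markers, which differed by 0.37 (SE 0.121). Both means were negative, against the rise that a lower share alone would give. The other means were -0.276 for smooth muscle, -0.0867 for epicardial, -0.086 for Schwann and neural, 0.0179 for endothelial and 0.393 for the 4 tested erythroid markers. These values cannot exclude a lower share together with a change in the other cells, which would also set fibroblast and macrophage markers apart. After removal of each library's trend with gene length the sarcomere median was -0.349 (camera adjusted p = 1.81e-12; adjusted p = 0.349 with an estimated correlation, against 0.327 before the removal). Of 10000 random lists matched on mean expression, 0% had a median as low, with a central range of -0.121 to 0.0712. This argues against a general fall at that expression as the whole cause, though random lists lack the correlation between sarcomere genes (estimated at 0.596). The 10 most abundant genes of each library made up 10.9% ± 0.320 of fragments with vehicle and 8.65% ± 0.634 with perhexiline. For that share the exact permutation test (two-sided) gave p = 0.1. Some fall of abundant transcripts stays open as part of the pattern. A loss of several cell types at once stays open, and a lower expression in cardiomyocytes may be involved but is a hypothesis.

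Mff was lower with perhexiline. In perhexiline replicate 1 the annotated copy held 867 fragments, against at most 28 in the other libraries, which is consistent with reads moved to the copy in that library. In perhexiline replicates 2 and 3 the highest sum over both loci was 210, against at least 573 in the vehicle libraries, and a lower expression cannot be told apart from reads dropped as ambiguous, since no value shows the dropped reads.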
